A study of Mus musculus with 8 samples.

How the data were processed

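The study measured RNA in mouse CD8+ T cells activated in culture for 24 or 48 h, in WT cells and in cells labelled dKO, with 2 libraries in each of the 4 groups. The authors deposited whole-number counts per gene symbol for each of the 8 libraries. Per the submitters' processing notes, reads were trimmed with cutadapt 1.18 and aligned with Bowtie2 2.2.5 to mm10. The program that counted reads, its annotation, the strand rule and any use of molecular identifiers are not given in the sources used here. The name of the deposited counts hints at reads from the 5' ends of RNAs, but whether only these were counted is not given either, so a count per gene need not cover all of its exons. Counts of antisense pairs such as Xist and Tsix can therefore hold reads of either gene. The table has 24976 gene symbols, 22981 of them with a count in some library. Its last entry has no name and equals the column total in all 8 libraries (50.0% of each column sum), so it was left out. Gene positions came from the GENCODE M21 and RefSeq mouse annotations, which held 23259 of the symbols.

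Total counts ran from 5000952 to 21686236 per library. A count of 0 allows a level of up to 3 counts, which is 0.138 to 0.600 counts per 1e6 counts (CPM) per library. Intervals and floors cover counting error only, and p-values measure the spread between these libraries only. CPM of single genes was scaled by the TMM factors, while the CPM of Xist, of the Y-linked genes and of Cd8a and Cd4 in the description of the libraries was taken over the total counts.

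Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. All libraries entered 1 fit with a mean per group, and filterByExpr with a minimum count of 10 kept 12742 genes. TMM scaling was used. The common dispersion was 0.0246, with 4 residual and 5.76 prior degrees of freedom. Genes were called at an adjusted p (Benjamini-Hochberg) below 0.05, with no minimum fold. The tests were two-sided, and the standard error (SE) is the absolute log2 fold change over the square root of F. The 6 comparisons were the genotype difference at 24 h, at 48 h and over both times, the genotype by time interaction, and 48 h against 24 h within each genotype label. For a gene with 1 to 3 counts in a group the ratio of counts is given with its exact counting interval (95%). Results of some single genes are not reported here.

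In total 29 gene lists were fixed. They cover NR4A receptors, naive, stem-like and memory genes, exhaustion, effector genes, cytokines and chemokines, type 2 and type 17 genes, genes induced by the T cell receptor, negative feedback, S phase, G2 and mitosis, and p53 and survival. They also cover glycolysis, oxidative phosphorylation, amino acid response genes, cholesterol synthesis, interferon response, trafficking, heat shock and unfolded proteins, replication-dependent histones, ribosomal proteins and ribosome biogenesis. The rest are neighbours of Nr4a1 and Nr4a2, RNAs encoded by mitochondria, and markers of CD8, CD4 or regulatory T, B, myeloid, NK or gamma delta T, and red, platelet or stromal cells. Lists were tested on log2 CPM (prior count 2) with camera of limma 3.58.1 at a preset correlation of 0.01, with p adjusted over the 26 lists that had at least 3 tested members. Of the others, 0 mitochondrial RNAs are in the table, 0 NK and gamma delta markers and 2 markers of CD4 or regulatory T cells were tested. Camera with an estimated correlation and fry were run beside it. Of 50 list results called with the preset correlation, 5 held with an estimated one: G2 and mitosis at 24 h and in both time comparisons, p53 and survival at 24 h, and histones at 24 h.

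The lists, comparisons, thresholds and the rule for named genes were set before the data were examined. The rule names Nr4a1, Nr4a2, Nr4a3 and Tcf7 always, and Slamf6, Pdcd1, Havcr2, Tox, Gzmb, Ifng, Il2 and Prf1 with their values. It adds, for each genotype and time comparison, up to 10 called genes in each direction with the largest change, where both libraries of a group lie above both of the other and the mean is at least 20 counts. Predicted genes without a symbol of their own are counted but not named. It also adds up to 4 members of each list with the smallest p in each genotype comparison and up to 10 called interaction genes.

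Tests on simulated data used the observed depths and dispersions, with 100 genes changed by 1 and 100 by 2 log2 units. At 48 h 60.0% and 95.0% of these were recovered and 3.1% of calls were false. The recovery at 24 h was 52.0% and 97.0% with 6.9% false, and over both times 86.0% and 100.0% with 7.5% false. For the interaction it was 18.0% and 80.0% with 5.8% false. For time it was 55.0% and 96.0% in WT with 11.2% false, and 55.0% and 99.0% in cells labelled dKO with 5.5% false. The simulated genes were drawn independently, each with 1 dispersion for all groups. The observed median absolute log2 difference between replicates was 0.364 in WT at 48 h and 0.149 in dKO at 48 h. The simulated rates therefore need not hold for these data. In camera a list of 40 genes shifted by 0.5 log2 units was called, and 1 of 200 unshifted lists passed at an unadjusted level of 0.05. That rate does not cover lists whose genes vary together. Replicates were checked for identity: their counts differed by more than counting error in all 4 groups (chi-square per degree of freedom 2.63 to 67.9), so no library was entered again as its own replicate. Whether replicate numbers pair samples across groups is not known. Correlations of replicate differences ran from -0.08 to 0.17, which does not settle it, and the main fit used no replicate block.

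Alternatives set in advance were other scalings (median-ratio factors of DESeq2 1.42.0, upper quartile, library size), no filter or a mean of at least 50 counts, DESeq2 and limma-voom tests, a replicate block, other thresholds (adjusted p below 0.10, or an absolute log2 fold change of at least 1), only the 4 libraries compared, and each library left out in turn. Chosen after seeing the data were autosomal genes only, WT 48 h replicate 2 thinned to 7021569 counts, and the fit without 286 genes of a common profile. These are genes whose log2 CPM followed the sum of 4 genes (Olfr70, Olfr722, Pcdhgb2 and Pcdhga3) within 0.15 log2 units (root mean square) over the 6 libraries other than WT at 24 h. Alternatives for values on a log scale with a pseudocount did not apply to counts.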

Results

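RNA was sequenced in bulk from mouse CD8+ T cells that had been activated in culture with antibodies against CD3 and CD28 together with IL-2. The cells were collected after 24 or 48 h. The labels name wild-type (WT) cells and cells labelled dKO, in which Cre recombinase under Cd8 control acts on floxed Nr4a1 and Nr4a2. These genes encode nuclear receptors that T cell receptor signals induce and that have been tied to T cell exhaustion. The 8 libraries form 4 groups of 2. Total counts were 6900893 and 5824552 in WT at 24 h, and 8278058 and 5000952 in the libraries labelled dKO at 24 h. At 48 h they were 7018314 and 21686236 in WT, and 6954913 and 7911611 in the libraries labelled dKO. Cd8a, which encodes a chain of the CD8 coreceptor, was counted at 447 to 991 counts per 1e6 counts (CPM) per library, and Cd4 at 0 to 2 counts per library.

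Some properties of the libraries moved with the groups. Xist, the RNA that silences an X chromosome in female cells, stood at 323 to 805 CPM in the 4 WT libraries and at 0.72 to 1.8 CPM in the 4 libraries labelled dKO. The sum of the Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty was 1.28 to 1.75 CPM in the WT libraries and 131 to 175 CPM in those labelled dKO. Every genotype comparison is therefore also a comparison of female-type with male-type transcripts. Across genes, the log2 CPM of replicates correlated at r = 0.965 in WT at 48 h and at 0.985 to 0.989 in the other 3 groups. Genes with symbols that begin with Rpl or Rps took 7.04% of the counts in WT 48 h replicate 2 (95% Wilson interval 7.03 to 7.06%). In replicate 1 of that group the same interval was 10.98 to 11.02%, and the share was 11.7 to 13.4% in the other 6 libraries. A set of 286 genes was chosen after the data were seen, for following the sum of 4 genes over the 6 libraries other than WT at 24 h. By that choice its members moved in nearly fixed proportion to one another there. It includes the muscle gene Csrp3 and the testis genes Ropn1, Odf4 and Tnp2, but also the oxidative phosphorylation gene Cox7b and the chemokine gene Ccl5. This set took 22.3% (Wilson interval 22.2 to 22.3%) and 23.4% (23.39 to 23.43%) of the counts in the WT libraries at 48 h, and 8.3 to 12.3% in the other 6.

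**Figure D1:**
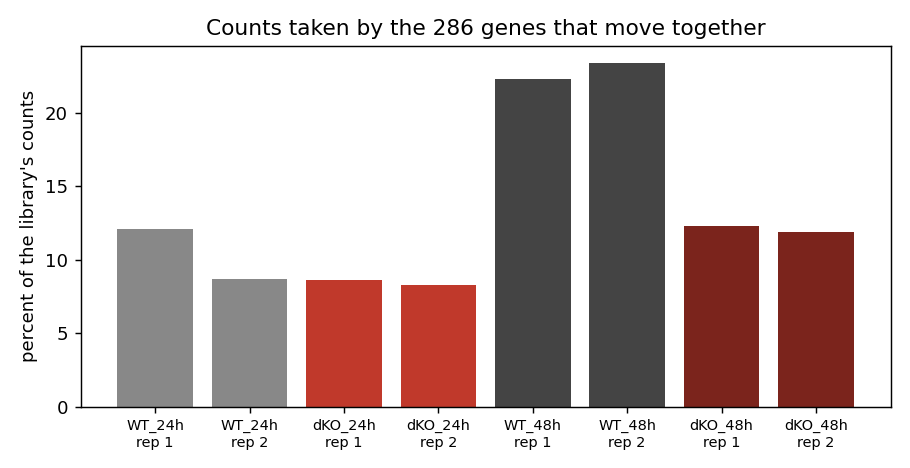
Percent of each library's counts (vertical axis, linear, from 0) taken by the 286 genes that moved in nearly fixed proportion, 1 bar per library, coloured by group. The bars of the WT libraries at 48 h stand at 22.3 and 23.4%, and the other 6 lie between 8.3 and 12.3%.

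The first question was whether the targeted genes were lower in the libraries labelled dKO. They were not, so these counts do not check the deletion. Nr4a2 (chromosome 2: 57106830 to 57124003, GRCm38/mm10) rose at 24 h from 54.5 ± 7.54 CPM in WT to 139 ± 4.71 CPM in the libraries labelled dKO (SD, n = 2 each). At 48 h it rose from 28.9 ± 6.06 to 76.4 ± 1.29 CPM (SD, n = 2 each). The log2 fold changes were 1.35 (SE 0.173, adjusted p = 0.00836) and 1.38 (SE 0.176, adjusted p = 0.00982) in edgeR. The call at 24 h was lost without any 1 of the 24 h libraries or of the dKO 48 h libraries (adjusted p = 0.051 to 0.185), and that at 48 h without dKO 48 h replicate 1 or 2 (0.137 and 0.149). Nr4a1 (chromosome 15: 101254269 to 101274795) was not called: 401 ± 177 CPM in WT against 520 ± 18.9 CPM at 24 h, and 830 ± 72.2 against 652 ± 24.7 CPM at 48 h (SD, n = 2 each). Its log2 fold changes were 0.37 (SE 0.265, adjusted p = 0.88) and -0.35 (SE 0.264, adjusted p = 0.38). At 24 h it was -0.03 without WT 24 h replicate 2. Nr4a3 (chromosome 4: 48045153 to 48086447), the related receptor that was not targeted, was not called either, at 0.12 at 24 h and -0.42 at 48 h (0.28 without WT 48 h replicate 2). The exons removed by Cre are not given in the sources used here, and counts per gene include exons that a floxed allele may keep. Directions below are therefore stated for the libraries labelled dKO. Tcf7 (chromosome 11: 52252371 to 52283014), which encodes TCF1, the factor of stem-like T cells that the series title names, was not called. It stood at 85.2 ± 1.3 CPM in WT against 63.5 ± 6.41 CPM at 24 h and at 63.8 ± 0.649 against 53.03 ± 2.05 CPM at 48 h (SD, n = 2 each). Over both times its log2 fold change was -0.35 (SE 0.097, adjusted p = 0.0572).

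**Figure D2:**
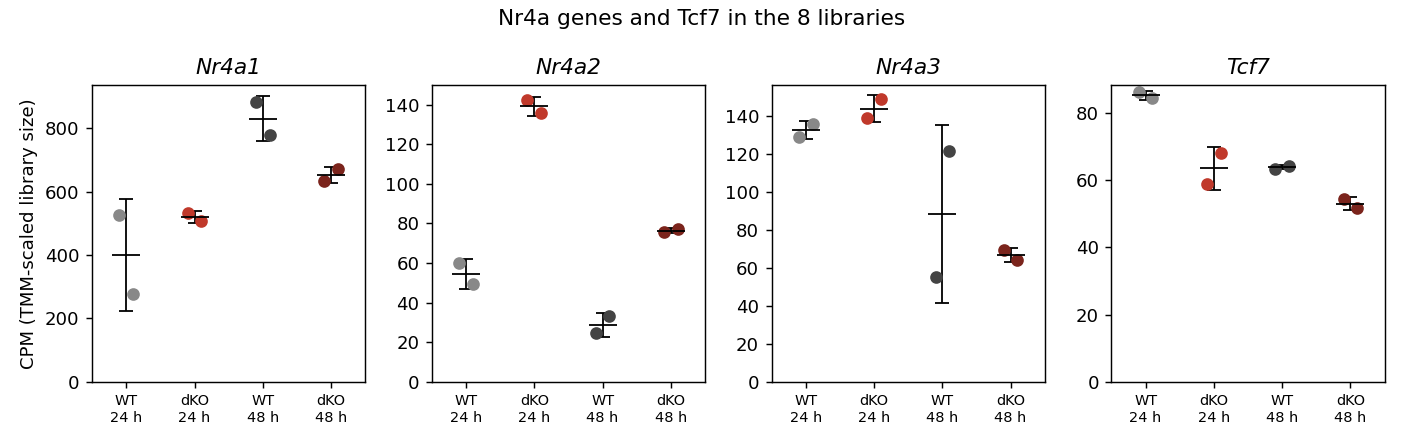
CPM (vertical axes, linear) of Nr4a1, Nr4a2, Nr4a3 and Tcf7 in each library (points) by group (horizontal axes), with the group mean and SD (n = 2). Nr4a2 means are 139 and 76.4 CPM in the libraries labelled dKO against 54.5 and 28.9 CPM in WT.

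At 24 h the comparison asks how the genotype label goes with the early response to activation. Among the named genes, secreted cytokines had the largest rises outside the sex chromosomes. Il3, a growth factor for blood cells, was at 80.2 ± 11.9 CPM in the libraries labelled dKO against 4.09 ± 0.0264 CPM in WT. Ccl1, a chemokine that binds CCR8, was at 152 ± 7.09 against 12.9 ± 0.097 CPM. Il2, the T cell growth factor, was at 50.2 ± 5.27 against 6.53 ± 0.304 CPM, and Ifng, the main type 1 effector cytokine, at 1171 ± 55.1 against 456 ± 30.5 CPM (SD, n = 2 in each group). Csf2, which encodes GM-CSF, had 131 counts against 3 over the libraries of each group, a ratio of 41.9 (95% counting interval 14 to 206, adjusted p = 0.00821).

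Of the 20 cytokine and chemokine genes tested at 24 h, 7 rose and 0 fell in the libraries labelled dKO, and 15 rose when adjusted over the list alone. The log2 fold changes were 4.29 for Il3 (SE 0.274, adjusted p = 6.66e-05), 3.56 for Ccl1 (SE 0.157, adjusted p = 3.9e-06) and 2.94 for Il2 (SE 0.292, adjusted p = 0.00162). The list as a whole was higher than other genes (median log2 0.85, camera adjusted p = 8.16e-22, adjusted p = 0.0634 with an estimated correlation). Among 34 genes of the p53 and cell survival list, 3 rose and 0 fell, and 9 rose and 1 fell when adjusted over the list alone. They were the cell cycle inhibitor Cdkn1a at 1.60 (SE 0.138), the stress gene Gadd45g at 1.85 (SE 0.198) and Bcl2l1, which encodes the survival protein BCL-XL, at 1.03 (SE 0.141). The list passed camera (median 0.31, adjusted p = 2.31e-07) and kept its call at adjusted p = 0.0295 with an estimated correlation. In the fits without WT 48 h replicate 1 or 2, 13 cytokine genes rose, and 10 p53 and survival genes rose and 1 fell. With WT 24 h replicate 1 or 2 left out, 3 cytokine genes and 1 p53 and survival gene rose, and with dKO 24 h replicate 1 left out, 4 cytokine genes.

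Genes of G2 and mitosis shifted together at 24 h. The median of the 50 tested was 0.52, only Ube2c rose (1.15, SE 0.184, adjusted p = 0.0294), and 25 rose when adjusted over the list alone. The camera adjusted p was 8.69e-22, and adjusted p = 0.0212 with an estimated correlation. Replication-dependent histone genes had a median of 0.74 over 53 genes. In edgeR 0 of them passed, 0 passed when adjusted over the list alone and 26 were higher at an unadjusted p under 0.05 (camera adjusted p = 8.16e-22, adjusted p = 0.0212 with an estimated correlation). Most of their RNAs lack poly(A), so they also respond to library preparation. Of 33 genes induced by the T cell receptor, Tnfrsf4 rose, which encodes the costimulatory receptor OX40 (1.27, SE 0.15), and 8 rose when adjusted over the list alone. Their camera adjusted p was 0.000394 (adjusted p = 0.0634 with an estimated correlation). Left-out libraries moved these counts: without WT 48 h replicate 1 or 2, 27 G2 and mitosis genes, 15 histone genes and 11 genes induced by the T cell receptor rose. The call of Ube2c was lost without any other single library, and that of Tnfrsf4 without any single 24 h library. With the replicate block 2 genes induced by the T cell receptor rose.

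Granzyme inhibitors were the called members of the 16 effector genes at 24 h: Serpinb9 at 1.25 (SE 0.157) and Serpinb6b at 1.61 (SE 0.199), with 5 higher and 1 lower when adjusted over the list alone. This list had a median of 0.17 and a camera adjusted p of 0.017 (adjusted p = 0.397 with an estimated correlation). It was not called without WT 24 h replicate 1 (0.0662), dKO 24 h replicate 1 (0.0593) or WT 48 h replicate 1 or 2 (0.0631 and 0.0613), nor with a mean of at least 50 counts (median -0.075, adjusted p = 0.25). Gzmb, which encodes granzyme B, was at 672 ± 31 against 375 ± 17.7 CPM (SD, n = 2) with a log2 fold change of 0.84 that did not pass (adjusted p = 0.118). Of 21 naive, stem-like and memory genes, Ly6c1 at 1.41 (SE 0.183) and Ly6c2 at 1.83 (SE 0.215) rose, 2 antigens of memory and activated CD8+ cells. The list was not called (camera adjusted p = 0.17), with 4 higher and 3 lower when adjusted over the list alone. Of the 17 exhaustion genes 0 passed in edgeR, with 5 higher and 1 lower at an unadjusted p under 0.05 and 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.234). Pdcd1 was at 0.34 (adjusted p = 0.676), Havcr2 at 1.09 (0.647), Tox at -0.29 (0.841), Slamf6 at 0.07 (0.973) and Prf1 at -0.05 (0.978). Outside the lists, the aspartic protease gene Ctse rose (2.79, SE 0.293). Nt5e, which encodes the ectoenzyme CD73, fell (-1.48, SE 0.208, adjusted p = 0.0145), and Spats2 fell (-3.22, SE 0.471, adjusted p = 0.0167). With WT 48 h replicate 1 or 2 left out, 4 effector genes rose and 1 fell, 4 naive, stem-like and memory genes rose and 3 fell, and 3 exhaustion genes rose and 1 fell. Both effector calls were lost without WT 24 h replicate 1 or 2 or dKO 24 h replicate 1. Those of the naive, stem-like and memory list were lost without WT 24 h replicate 1 or 2 or dKO 24 h replicate 2, and 1 rose without dKO 24 h replicate 1. In the fit scaled by library size alone, 1 effector gene and 1 naive, stem-like and memory gene fell.

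In total 55 of 12742 tested genes were called at 24 h, 46 higher and 9 lower in the libraries labelled dKO, with 6 of them on X or Y. Leaving out 1 library moved this count by over 1.5 times in each of the 8 cases. It was 14 and 13 without WT 24 h replicate 1 or 2, 18 and 26 without dKO 24 h replicate 1 or 2, 32 without either dKO 48 h replicate, and 368 and 371 without WT 48 h replicate 1 or 2.

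At 48 h the same comparison was made at a later point of activation. Of the 20 cytokine and chemokine genes, 9 rose and 1 fell in the libraries labelled dKO. Ccl1 (chromosome 11: 82176657 to 82305690) was at 24.1 ± 2.8 against 4.68 ± 0.0897 CPM in WT, and Il3 (chromosome 11: 54265303 to 54267277) at 18.7 ± 3.27 against 3.29 ± 1.38 CPM. Il2 (chromosome 3: 37120523 to 37125959) was at 12.04 ± 0.863 against 3.005 ± 1.79 CPM, and Csf2 (chromosome 11: 54247271 to 54249667) at 6.42 ± 0.813 against 1.37 ± 1.2 CPM (SD, n = 2 in each group). Batf3, a transcription factor linked to memory CD8+ cells, was at 58.0 ± 0.315 against 9.90 ± 2.91 CPM (SD, n = 2).

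**Figure D3:**
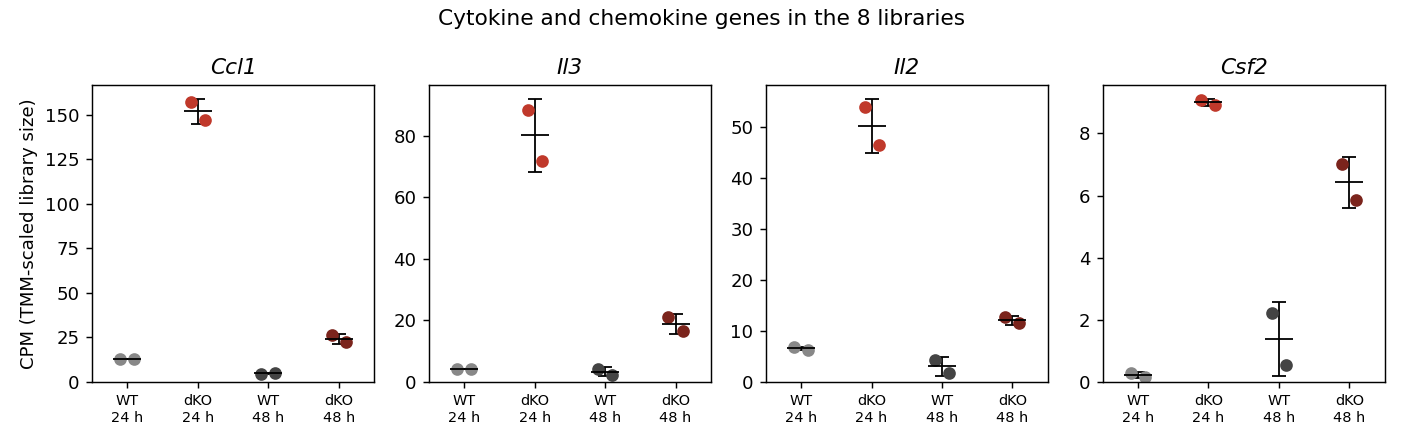
CPM (vertical axes, linear) of Ccl1, Il3, Il2 and Csf2 in each library (points) by group (horizontal axes), with the group mean and SD (n = 2). Means in the libraries labelled dKO exceed those in WT at both times, as 152 against 12.9 CPM for Ccl1 at 24 h.

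Adjusted over the list alone, 13 of the 20 cytokine and chemokine genes rose and 1 fell at 48 h, against 9 and 1 over all genes. Examples are Il3 at 2.64 (SE 0.281, adjusted p = 0.00264), Ccl1 at 2.35 (SE 0.169, adjusted p = 0.000236) and Il2 at 2.22 (SE 0.333, adjusted p = 0.0136). The member that fell was Ccl5, a chemokine of effector cells, at -0.97 (SE 0.174, adjusted p = 0.0147), named after its values were seen. It belongs to the 286 genes in fixed proportion. Ifng did not pass at 0.64 (adjusted p = 0.0664). The list passed camera (median 0.675, adjusted p = 6.32e-07), but not with an estimated correlation (adjusted p = 0.571). Of the 33 genes induced by the T cell receptor, 5 rose and 1 fell, with 6 and 4 when adjusted over the list alone. Batf3 was at 2.60 (SE 0.318) and Junb, an AP-1 subunit, at 0.72 (SE 0.16). The camera test of that list did not pass (adjusted p = 0.203). Leaving out WT 48 h replicate 1 gave 15 risen cytokine genes, and 10 risen and 9 fallen genes induced by the T cell receptor. Leaving out either dKO 48 h replicate gave 2 risen and 0 fallen cytokine genes and ended the calls in the other list. In that list 8 rose without WT 48 h replicate 2, and 2 rose without either dKO 24 h replicate. Library size scaling alone gave 14 risen cytokine genes and 8 risen genes induced by the T cell receptor.

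Several genes of the naive, stem-like and memory list moved in opposite directions at 48 h. Of 21 tested, 2 rose and 5 fell, with 3 and 5 when adjusted over the list alone. Among those that fell was Il6ra, a receptor chain of resting T cells, at -1.81 (SE 0.254, adjusted p = 0.0126). Ly6c1 at 1.89 (SE 0.181) and Ly6c2 at 2.19 (SE 0.215) rose. The list was not called as a whole (camera adjusted p = 0.403). Of 17 exhaustion genes, 0 rose and 3 fell, with 1 higher and 3 lower when adjusted over the list alone. They were Pdcd1, which encodes the inhibitory receptor PD-1 (-0.64, SE 0.144, adjusted p = 0.0231), Tigit, another inhibitory receptor (-0.73, SE 0.18, adjusted p = 0.0315), and Tox, a regulator of exhausted cells (-0.86, SE 0.167, adjusted p = 0.0162). Pdcd1 was at 71.9 ± 5.53 against 112 ± 10.1 CPM and Tox at 8.40 ± 0.12 against 15.2 ± 0.0102 CPM (SD, n = 2). The whole exhaustion list was not called (camera adjusted p = 0.93), and Havcr2 was at -0.72 (adjusted p = 0.258). Havcr2 was at 0.06 without WT 48 h replicate 2. When WT 48 h replicate 1 was left out, 5 naive, stem-like and memory genes rose and 7 fell, and 4 exhaustion genes rose and 4 fell. When either dKO 48 h replicate was left out, all falls in both lists lost their call. In the naive, stem-like and memory list 3 fell without dKO 24 h replicate 2, and in the exhaustion list 1 fell without either dKO 24 h replicate and 1 rose without WT 48 h replicate 2. With library size alone, 4 naive, stem-like and memory genes rose, and 2 exhaustion genes rose and 1 fell.

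Of 16 effector genes, 4 rose and 0 fell at 48 h, with 8 and 1 when adjusted over the list alone. Gzmc, a granzyme of strongly stimulated cells, was at 3.21 (SE 0.499) and Id2, a regulator of effector differentiation, at 0.87 (SE 0.182). Gzmb at 0.52 (adjusted p = 0.0845), Prf1 at -0.29 (0.319) and Slamf6 at 0.15 (0.692) did not pass. The effector list was just called (median 0.28, camera adjusted p = 0.0487, adjusted p = 0.571 with an estimated correlation). It was not called without the 286 genes (adjusted p = 0.0583), without WT 48 h replicate 2 (0.186), with the replicate block (0.0569) or with a mean of at least 50 counts (0.359). Of 34 genes in the p53 and survival list, 7 rose and 1 fell, with 8 and 2 when adjusted over the list alone. Gadd45g was at 1.69 (SE 0.184), Bcl2a1a, a BCL2 relative that promotes survival, at 1.20 (SE 0.28) and Trp53inp1 at -0.87 (SE 0.155). That list did not pass camera (adjusted p = 0.0587). Leaving out WT 48 h replicate 1 gave 9 risen and 2 fallen effector genes and 13 risen and 8 fallen p53 and survival genes, and leaving out WT 48 h replicate 2 gave 4 and 3 effector genes. The effector calls were lost without either dKO 48 h replicate. Of the effector genes 8 rose with library size alone. Of the p53 and survival genes 2 rose without either WT 24 h replicate, 1 without either dKO 24 h replicate or dKO 48 h replicate 1, and 0 without dKO 48 h replicate 2.

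Of the lists of energy metabolism and protein synthesis, those of oxidative phosphorylation, ribosomal proteins and ribosome biogenesis were called by camera at 48 h, and 0 of these 3 with an estimated correlation. Of 76 oxidative phosphorylation genes, 6 rose and 1 fell, and 0 passed when adjusted over the list alone. The complex II subunit gene Sdhc was at 0.79 (SE 0.168) and the complex I subunit gene Ndufs3 at 0.67 (SE 0.181), while the member that fell, Cox7b, belongs to the 286 genes. The list median was 0.295 (camera adjusted p = 8.67e-07, adjusted p = 0.72 with an estimated correlation). The 75 ribosomal protein genes had a median of 0.33. In edgeR 0 passed, 0 passed when adjusted over the list alone and 11 were higher at an unadjusted p under 0.05 (camera adjusted p = 3.4e-07, adjusted p = 0.72 with an estimated correlation). Neither list was called without WT 48 h replicate 2, where the medians were 0.03 (adjusted p = 0.186) and -0.04 (adjusted p = 0.342). Of 43 ribosome biogenesis genes, 6 rose and 0 fell, with 10 and 0 when adjusted over the list alone, among them Rrp9 at 0.90 (SE 0.185) and Mrto4 at 0.77 (SE 0.163). Their camera adjusted p was 0.0139 (adjusted p = 0.571 with an estimated correlation), 0.213 without WT 48 h replicate 1 and 0.0771 with a mean of at least 50 counts. Of 30 glycolysis genes, 3 fell, with 3 lower when adjusted over the list alone. They were Pfkfb3, an activator of glycolysis, at -1.17 (SE 0.204), Eno3 at -0.68 (SE 0.135) and Hif1a, the oxygen-sensing factor, at -0.52 (SE 0.144), while the list itself was not called (camera adjusted p = 0.962). Of 30 cholesterol synthesis genes, Fads2 (1.96, SE 0.429), Fdps (0.56, SE 0.139) and Ebp (0.54, SE 0.148) rose and the list was not called (camera adjusted p = 0.113). Single-gene counts in these lists differed with the library left out. Without WT 48 h replicate 1, 58 oxidative phosphorylation genes rose and 1 fell, 68 ribosomal protein genes rose, 15 ribosome biogenesis genes rose and 8 fell, 5 glycolysis genes rose and 7 fell, and 9 cholesterol synthesis genes rose and 3 fell. All calls in these 5 lists were lost without either dKO 48 h replicate, and those in the oxidative phosphorylation and ribosome biogenesis lists also without either dKO 24 h replicate. With either WT 24 h replicate left out, 1 oxidative phosphorylation gene, 2 ribosomal protein genes and 1 cholesterol synthesis gene rose. Of the ribosome biogenesis genes 3 rose without WT 24 h replicate 2. With either dKO 24 h replicate left out, 1 glycolysis gene fell and 1 cholesterol synthesis gene rose, and without WT 48 h replicate 2, 1 oxidative phosphorylation gene rose and 2 fell. Scaled by library size alone, 28 oxidative phosphorylation genes rose and 1 fell, 16 ribosomal protein and 12 ribosome biogenesis genes rose, and 2 glycolysis genes rose and 1 fell. With the replicate block 3 oxidative phosphorylation genes rose.

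**Figure D4:**
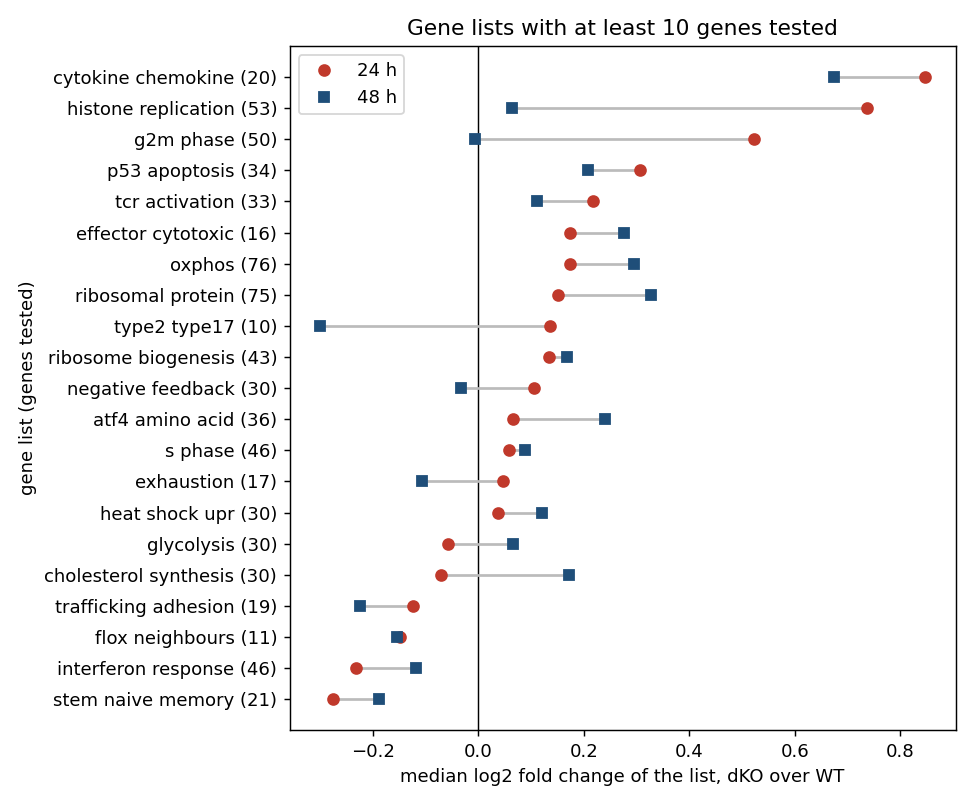
Median log2 fold change of the tested members of each gene list (horizontal axis) at 24 h (circles) and 48 h (squares), libraries labelled dKO against WT, for lists with at least 10 genes tested. The cytokine list stands at 0.85 and 0.675, and the G2 and mitosis list at 0.52 and -0.01.

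In total 1430 genes were called at 48 h, 406 higher and 1024 lower in the libraries labelled dKO, with 61 on X or Y. Of the 1024 lower genes, 281 (27.4%) belong to the set of 286 in fixed proportion, and without these 286 genes 872 were called, 278 higher and 594 lower. The set was chosen over libraries that include those at 48 h, so its direction here follows from that choice. Scaled by library size alone, 2531 were called, 1615 higher and 916 lower. Leaving out a library gave 1162 without WT 48 h replicate 2 but 6521 without WT 48 h replicate 1. The count fell to 18 and 15 without dKO 48 h replicate 1 or 2, where more were higher than lower (15 and 3, 13 and 2), to 513 and 491 without dKO 24 h replicate 1 or 2, and to 874 and 863 without WT 24 h replicate 1 or 2.

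Of the 46 genes higher at 24 h, 39 were also higher at 48 h, where 1.47 would be shared by chance, and 8 of the 9 lower genes were also lower (0.72 by chance). Across the 12742 genes, which are not independent replicates, the log2 fold changes at 24 and 48 h correlated at r = 0.48 (Spearman 0.41).

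Over both times, 4 libraries against 4, cytokine genes were again among the largest autosomal rises. Ccl1 was at 2.96 (SE 0.115, adjusted p = 6.84e-07), Il3 at 3.47 (SE 0.196, adjusted p = 1.57e-05), Il2 at 2.58 (SE 0.221, adjusted p = 0.000331), and Ifng (chromosome 10: 118441046 to 118445892) at 1.00 (SE 0.142, adjusted p = 0.00723). Il1a, an inflammatory cytokine outside the list, was at 2.74 (SE 0.332, adjusted p = 0.00319). Of the 20 cytokine genes, 14 rose and 1 fell, with 16 and 1 when adjusted over the list alone (median 0.695, camera adjusted p = 1.5e-12, adjusted p = 0.159 with an estimated correlation). The calls of Ccl1 and Il3 at 24 h, at 48 h and over both times held in every alternative run. The count of risen cytokine genes was 8 without WT 24 h replicate 1, 6 and 7 without dKO 24 h replicate 1 or 2, and 6 without either dKO 48 h replicate.

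Gzmb (chromosome 14: 56258838 to 56262260) rose over both times (0.68, SE 0.127, adjusted p = 0.021), as 1 of 5 effector genes of 16, while the NK receptor gene Klrd1 fell (-0.71, SE 0.152). Adjusted over the list alone 6 rose and 2 fell (camera adjusted p = 0.0168, adjusted p = 0.426 with an estimated correlation, 0.0972 without WT 48 h replicate 2, and 0.28 with a mean of at least 50 counts). Among 21 naive, stem-like and memory genes, 4 rose and 6 fell, with 4 and 9 when adjusted over the list alone. Eomes, a factor of memory and exhausted cells, was at 0.97 (SE 0.175). The list was not called (camera adjusted p = 0.188). Among 17 exhaustion genes, 3 rose and 2 fell, with 4 and 2 when adjusted over the list alone. Nrp1 at 0.76 (SE 0.166) and Pdcd1lg2, which encodes the PD-1 ligand PD-L2, at 0.60 (SE 0.103) rose, and Tigit (-0.73, SE 0.128) and Tox (chromosome 4: 6686353 to 6991557, -0.57, SE 0.116, adjusted p = 0.0252) fell. That list was not called (camera adjusted p = 0.886), and Pdcd1 was at -0.15 (adjusted p = 0.352). Leaving out WT 48 h replicate 1 gave 8 risen and 1 fallen effector genes, 5 and 12 naive, stem-like and memory genes, and 4 and 4 exhaustion genes, and leaving out WT 48 h replicate 2 gave 5 and 3 effector genes. With 1 of the other 6 libraries left out, 2 to 5 effector genes rose and 0 fell, 2 to 3 naive, stem-like and memory genes rose and 1 to 3 fell, and 0 to 1 exhaustion genes rose and 0 to 1 fell.

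The G2 and mitosis list and the p53 and survival list were also called over both times. Of 50 G2 and mitosis genes, 7 rose and 0 fell, with 17 and 1 when adjusted over the list alone, among them Ube2c at 0.80 (SE 0.126) and Cdc20 at 0.60 (SE 0.112). The camera adjusted p was 2.86e-07 (adjusted p = 0.0863 with an estimated correlation). At 48 h alone that list was not called (median -0.006, camera adjusted p = 0.546): 2 rose and 1 fell, with 0 when adjusted over the list alone, 15 and 12 without WT 48 h replicate 1, and no call without any 1 library labelled dKO. Scaled by library size alone, 12 rose and 0 fell at 48 h (median 0.172, camera adjusted p = 0.316), and 16 rose over both times. With the replicate block 2 rose and 0 fell at 48 h (median 0.005). The S phase list was not called over both times (median 0.055, camera adjusted p = 0.223). Of 34 p53 and survival genes, 8 rose and 2 fell, with 14 and 2 when adjusted over the list alone. Cdkn1a was at 1.08 (SE 0.096) and Bcl2l1 at 0.85 (SE 0.099), with camera adjusted p = 0.00012 (adjusted p = 0.0863 with an estimated correlation). Of 33 genes induced by the T cell receptor, 8 rose and 0 fell, with 10 and 3 when adjusted over the list alone (camera adjusted p = 0.0141, adjusted p = 0.159 with an estimated correlation, 0.102 without WT 48 h replicate 1). Nt5e (chromosome 9: 88327197 to 88372092) was at -1.57 (SE 0.157, adjusted p = 0.00116), and Spats2 (chromosome 15: 99125916 to 99213215), which lies on the chromosome of Nr4a1, was at -3.28 (SE 0.339, adjusted p = 0.00127). Of 11 tested neighbours of Nr4a1 and Nr4a2, Cytip on chromosome 2 fell (-0.43, SE 0.096, adjusted p = 0.0288), a call lost with library size alone and without WT 24 h replicate 1 or any 1 library labelled dKO. When WT 48 h replicate 1 or 2 was left out, 22 and 21 G2 and mitosis genes, 18 and 13 p53 and survival genes, and 12 in each case of the genes induced by the T cell receptor rose. With 1 of the other 6 libraries left out, 0 to 6, 3 to 4 and 1 to 5 rose.

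The total over both times was 994 called genes, 291 higher and 703 lower in the libraries labelled dKO, with 43 on X or Y. Without the 286 genes in fixed proportion it was 580, 219 higher and 361 lower, and library size scaling gave 680 higher and 610 lower. It moved by over 1.5 times without WT 24 h replicate 1 (224), dKO 24 h replicate 1 or 2 (56 and 93), WT 48 h replicate 1 or 2 (5606 and 1574) and either dKO 48 h replicate (66 each). Without any 1 library labelled dKO more genes were higher than lower: 45 and 11 or 66 and 27 without dKO 24 h replicate 1 or 2, and 55 and 11 or 51 and 15 without dKO 48 h replicate 1 or 2.

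The interaction asks whether the genotype difference changed between 24 and 48 h. No gene passed in edgeR (0 of 12742, with 1575 at an unadjusted p under 0.05 and a smallest adjusted p of 0.369), and DESeq2 and limma-voom called 0 as well. Ccl1 was at -1.21, Il3 at -1.65, Ifng at -0.72 and Pdcd1 (chromosome 1: 94038305 to 94052553) at -0.98 (SE 0.204, adjusted p = 0.369), so a falling genotype difference with time was not shown for them. This count depended on the filter and on single libraries. With no filter on low counts 170 genes were called, 11 higher and 159 lower. Genes were also called without WT 24 h replicate 1, WT 48 h replicate 1 or WT 48 h replicate 2, but not without any other single library. Among simulated genes with a difference of 1 log2 unit, 18.0% were recovered, and 80.0% at 2 units.

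From 24 to 48 h in WT cells, the comparison follows the course of activation. Gzmb rose from 375 ± 17.7 to 2265 ± 46.1 CPM (SD, n = 2), a log2 change of 2.59 (SE 0.19, adjusted p = 0.000523). Spp1, which encodes osteopontin, was at 4.85 (SE 0.465, adjusted p = 0.000862) and Cd80, a costimulatory ligand, at 3.95 (SE 0.292, adjusted p = 0.000523). Nr4a1 rose (1.05, SE 0.267, adjusted p = 0.0321), while Nr4a2 (-0.90, SE 0.176, adjusted p = 0.00889) and Il2 (-1.34, SE 0.353, adjusted p = 0.0375) fell. The WT libraries spread widely for Nr4a1 at 24 h, with 525.82 and 275.82 CPM, against 881.05 and 778.94 CPM at 48 h. Spry1, an inhibitor of receptor signalling, fell (-2.31, SE 0.199), as did Utf1 (-2.83, SE 0.27). Tcf7 (-0.42, adjusted p = 0.082), Slamf6 (-0.74, 0.0767) and Ifng (-0.13, 0.751) did not pass. Of 16 effector genes, 2 rose and 1 fell, with 3 and 6 when adjusted over the list alone. The effector list was not called (median -0.350, camera adjusted p = 0.708). Its counts were 2 and 5 without WT 48 h replicate 1, and 5 and 3 without replicate 2. Of 20 cytokine genes, 3 rose and 7 fell, with 5 and 7 when adjusted over the list alone (median -0.206, camera adjusted p = 0.494). Of these 4 fell without WT 24 h replicate 1, and 6 rose without WT 48 h replicate 2. Of 17 exhaustion genes, 2 rose and 6 fell, the same counts as when adjusted over the list alone (median -0.109, camera adjusted p = 0.315). Of these 4 rose without WT 48 h replicate 1, and 1 rose without any 1 library of the other 3 groups. Of 33 genes induced by the T cell receptor, 5 rose and 9 fell, with 6 and 12 when adjusted over the list alone (median -0.170, camera adjusted p = 0.315). The counts were 3 and 3 without either WT 24 h replicate, 4 and 4 without any 1 library labelled dKO, and 9 and 12 without WT 48 h replicate 1. Library size scaling alone gave 2 risen and 16 fallen genes in that list, 2 and 8 effector genes and 1 and 7 exhaustion genes. With the replicate block 1 exhaustion gene rose. Ifng was at 0.09 without WT 48 h replicate 2.

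Of 50 G2 and mitosis genes, 45 rose and 0 fell with time in WT, and 47 rose when adjusted over the list alone. Ccnb2, a mitotic cyclin, was at 3.08 (SE 0.251, adjusted p = 0.000672), and the list kept its call (median 1.12, camera adjusted p = 7.68e-30, adjusted p = 0.0153 with an estimated correlation). Other list members given for the time comparisons were named after their values were seen. Of 30 glycolysis genes, 8 rose and 0 fell, the same counts as when adjusted over the list alone, such as Bnip3 at 1.53 (SE 0.26) (camera adjusted p = 0.00472, adjusted p = 0.589 with an estimated correlation). Of 30 cholesterol synthesis genes, 4 rose and 0 fell, with 13 and 0 when adjusted over the list alone, including the fatty acid desaturase gene Scd1 at 2.90 (SE 0.475) (camera adjusted p = 0.000317, adjusted p = 0.572 with an estimated correlation). Of 46 interferon response genes, 1 rose and 10 fell, with 1 and 13 when adjusted over the list alone, among them the antiviral gene Ifit3 at -3.02 (SE 0.587) (camera adjusted p = 0.00472, adjusted p = 0.696 with an estimated correlation). Of 30 negative feedback genes, 1 rose and 5 fell, with 1 and 11 when adjusted over the list alone (camera adjusted p = 0.0464, adjusted p = 0.572 with an estimated correlation). Without WT 24 h replicate 1 the glycolysis (adjusted p = 0.0709) and interferon (0.24) calls were lost, and without WT 48 h replicate 1 the interferon call (0.0539). The negative feedback call was lost without the 286 genes in fixed proportion (0.0624), WT 24 h replicate 2 (0.072) or WT 48 h replicate 1 or 2 (0.121 and 0.0872), and with the replicate block (0.0544) or library size alone (0.0981). When WT 24 h replicate 1 or 2 was left out, 28 and 25 G2 and mitosis genes, 4 and 3 glycolysis genes and 2 and 1 cholesterol synthesis genes rose, and 1 negative feedback gene fell in each case. Of the interferon genes 5 fell without WT 24 h replicate 1 and 16 without WT 48 h replicate 2. When WT 48 h replicate 1 or 2 was left out, 13 and 10 glycolysis genes and 13 and 9 cholesterol synthesis genes rose, and 10 negative feedback genes fell in each case. Leaving out any 1 library labelled dKO gave 5 risen glycolysis genes and 3 fallen negative feedback genes. Scaled by library size alone, 4 glycolysis genes rose and 1 fell (median -0.101, against 0.265) and 2 cholesterol synthesis genes rose and 1 fell (median -0.077, against 0.295), with camera adjusted p = 0.0416 and 0.0156, and 20 interferon and 13 negative feedback genes fell.

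In WT cells 1449 genes were called between the times, 1003 higher and 446 lower at 48 h. The 286 genes in fixed proportion are all among the 1003. Scaled by library size alone, 3366 were called, 725 higher and 2641 lower. The count moved by over 1.5 times without WT 24 h replicate 1 or 2 (786 and 595) and without WT 48 h replicate 1 or 2 (4212 and 2986).

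In the cells labelled dKO the same time comparison showed the rise of Gzmb from 672 ± 31 to 3245 ± 107 CPM (SD, n = 2), a log2 change of 2.27 (SE 0.187, adjusted p = 0.000948). Spp1 rose (5.01, SE 0.446) and Batf3 rose (3.61, SE 0.35). Of 20 cytokine genes, 3 rose and 9 fell, with 4 and 11 when adjusted over the list alone, including Ccl1 at -2.66 (SE 0.148, adjusted p = 0.000107) and Il2 at -2.06 (SE 0.273, adjusted p = 0.00418). Ifng was at -0.85 (adjusted p = 0.0505). The list was called (median -0.63, camera adjusted p = 0.00913), but not with an estimated correlation (adjusted p = 0.667), nor without WT 24 h replicate 1 or 2 (0.0591 and 0.062) or dKO 24 h replicate 1 (0.068). Of 17 exhaustion genes, 1 rose and 8 fell, with 2 and 9 when adjusted over the list alone. Pdcd1 was at -0.63 (SE 0.145, adjusted p = 0.0482) and Tox at -0.80 (SE 0.171, adjusted p = 0.0356), and the member that rose was Ctla4, another inhibitory receptor, at 2.48 (SE 0.226). The median of the exhaustion list was -0.65 (camera adjusted p = 0.000747, adjusted p = 0.135 with an estimated correlation). With 1 of the 4 libraries labelled dKO left out, 1 cytokine gene rose and 2 to 4 fell, and 1 exhaustion gene rose and 0 to 1 fell. With either WT 24 h replicate left out, 1 cytokine gene rose and 9 fell, and with either WT 48 h replicate left out, 2 exhaustion genes rose and 10 fell. With library size alone or the replicate block 1 cytokine gene rose.

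The G2 and mitosis list and the cholesterol synthesis list were called with time in the cells labelled dKO too. Of 50 G2 and mitosis genes, 23 rose and 0 fell, with 32 and 0 when adjusted over the list alone, and the call was kept (median 0.71, camera adjusted p = 1.22e-18, adjusted p = 0.0381 with an estimated correlation). Of 30 cholesterol synthesis genes, 13 rose and 0 fell, with 18 and 0 when adjusted over the list alone. Scd1 was at 2.84 (SE 0.43) and Fads2, a fatty acid desaturase gene, at 2.23 (SE 0.475), and the camera adjusted p was 9.38e-11 (adjusted p = 0.125 with an estimated correlation). Of 30 glycolysis genes, 4 rose and 0 fell, with 8 and 0 when adjusted over the list alone (camera adjusted p = 9.21e-06, adjusted p = 0.186 with an estimated correlation). Of 33 genes induced by the T cell receptor, 4 rose and 7 fell, with 6 and 14 when adjusted over the list alone (camera adjusted p = 0.0281, adjusted p = 0.186 with an estimated correlation). That call was lost without dKO 24 h replicate 2 (0.0654) or dKO 48 h replicate 1 (0.0717). Leaving out either WT 48 h replicate gave 36 risen G2 and mitosis genes, 21 cholesterol synthesis genes and 13 to 14 glycolysis genes, with 7 risen and 16 fallen genes induced by the T cell receptor. With 1 of the 4 libraries labelled dKO left out, 6, 1 to 2 and 0 to 1 rose in the first 3 lists, and 1 rose and 0 to 2 fell in the last. In the last, 2 rose without either WT 24 h replicate. Library size scaling alone gave 8 risen cholesterol synthesis genes, and 2 risen and 10 fallen genes in the last list. With the replicate block 2 rose in the last.

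In the cells labelled dKO 463 genes were called between the times, 224 higher and 239 lower at 48 h, and 2 of the 286 genes in fixed proportion were among the higher. DESeq2 gave 367 higher and 253 lower, and library size scaling 143 higher and 596 lower of 739. The count fell to 34 and 69 without dKO 24 h replicate 1 or 2 and to 42 and 32 without dKO 48 h replicate 1 or 2, and rose to 3303 without either WT 48 h replicate. Without WT 24 h replicate 1 or 2 the balance turned, and more genes were higher than lower. Between the genotypes, 139 of the genes that rose with time were shared (17.6 by chance) and 120 of those that fell (8.37 by chance). The log2 changes with time correlated at r = 0.50 across genes (Spearman 0.43).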

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

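The tests of RNA from other cell types and of donor sex, and the count of called genes near Nr4a1 and Nr4a2, were chosen only after the result was seen, while the interaction test, the segment test and the fits without 1 library were planned.

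For 7 gene lists the genotype difference at 48 h differed from that at 24 h by camera on the interaction term. EdgeR called 0 genes (1575 at an unadjusted p under 0.05, DESeq2 0, limma-voom 0). EdgeR called 170 with no filter, and some without WT 24 h replicate 1 or WT 48 h replicate 1 or 2. None of the 7 passed with an estimated correlation. The median interaction of the cytokine and chemokine genes was -0.506 (camera adjusted p = 0.00661, adjusted p = 0.738 with an estimated correlation). That of the G2 and mitosis genes was -0.447 (camera adjusted p = 5.86e-07, adjusted p = 0.234 with an estimated correlation). Replication-dependent histone genes were at -0.636 (camera adjusted p = 2.13e-05, adjusted p = 0.28 with an estimated correlation). Cholesterol synthesis genes were at 0.222 (camera adjusted p = 0.00732, adjusted p = 0.668 with an estimated correlation), and the CD8 marker genes at 0.540 (camera adjusted p = 0.00661, adjusted p = 0.668 with an estimated correlation). Oxidative phosphorylation genes were at 0.105 (camera adjusted p = 0.00713, adjusted p = 0.816 with an estimated correlation), and ribosomal protein genes at 0.152 (camera adjusted p = 0.000235, adjusted p = 0.816 with an estimated correlation). Without WT 48 h replicate 2 these last medians were -0.138 (adjusted p = 0.521) and -0.209 (adjusted p = 0.649). Both also lost their call without WT 24 h replicate 1 (0.287 and 0.184), and the oxidative phosphorylation genes without dKO 24 h replicate 1 (0.0928). The cytokine call was lost without WT 24 h replicate 1 or 2 (0.065 and 0.0526), dKO 24 h replicate 1 (0.157), WT 48 h replicate 1 (0.404) or dKO 48 h replicate 2 (0.09). The CD8 marker call was lost without WT 24 h or dKO 24 h replicate 1 (0.065 and 0.0521), and the cholesterol call without WT 48 h replicate 1 (0.0592) or with a mean of at least 50 counts (0.053).

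The higher cytokine and chemokine genes in the libraries labelled dKO (7 of 20 rose at 24 h and 9 at 48 h, or 3 without either WT 24 h replicate to 13 without either WT 48 h replicate, and 2 without either dKO 48 h replicate to 15 without WT 48 h replicate 1) were weighed against other sources. That the risen genes lie in a chromosome segment carried with the floxed alleles is argued against by position, since 0.0% of the 10 list members higher at either time lie within 20 Mb of Nr4a1 or Nr4a2. Gene positions do not depend on the counts, so this segment test takes from the data only which genes rose. A gene of such a segment acting on the risen genes from there was not tested and stays open. Over both times 25 of the 302 tested genes within 20 Mb were called (8.3%, against 7.8% elsewhere). Among them were Spats2 (-3.28, SE 0.339) at 2.13 Mb from Nr4a1 and Cytip (-0.43, SE 0.096) at 1.02 Mb from Nr4a2. RNA from CD4 T cells is argued against as the source of the summed gain of these 10 genes, which was at least 1206.8 CPM at 24 h and 523.0 CPM at 48 h: the upper 95% counting limit of Cd4 in the libraries labelled dKO was 0.06% and 0.10% of that. Zbtb7b stood at 0.033 to 0.152% of Cd8a in these libraries, Cd40lg at 0.0381 to 0.19% and Foxp3 at 0.204 to 0.381% (0.398 to 0.568% in WT), while Ctsz, which other T cells also express, stood at 4.9 to 6.16% (3.84 to 5.25% in WT). RNA from B or myeloid cells cannot be told apart from a difference of the CD8+ cells. Of 32 markers of these cells the highest in a library labelled dKO, Cst3, stood at 8.78% of Cd8a (6.61 to 8.78%, and 4.76 to 7.71% in WT) and Cd74, which rose at 48 h, at 1.14 to 2.15% (0.692 to 1.28% in WT). T cells also express both, and the share of other cells that the cytokine counts would need is not known. The next, Cd14, stood at 0.463 to 0.748%, and 10 markers had no count in the libraries labelled dKO. Some of these, such as Lyz2, C1qa and S100a8, had none in WT either, so they do not compare the genotypes. Neither the B nor the myeloid list was called at 24 or 48 h, but only 3 members of each were tested. Outside these lists Epcam, an epithelial marker, stood at 1.123 to 1.421% of Cd8a in WT and 1.179 to 2.313% in the libraries labelled dKO, and Pecam1, an endothelial marker, at 0.762 to 1.920% and 0.685 to 0.816%. RNA from epithelial or endothelial cells was not tested and stays open. The sex of the donor animals and the genotype label cannot be told apart, because sex transcripts followed the label in 8 of 8 libraries. A difference made by the loss of Nr4a1 and Nr4a2 stays open beside it, as a hypothesis that these libraries do not test apart from sex.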

How the results depend on the processing

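The fits on autosomes, with WT 48 h replicate 2 thinned, and without the 286 genes of the common profile were chosen only after the data were seen; all other alternatives were planned. For the values that changed, the cause was not tested unless stated.

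No gene named or always listed turned direction where it was called with or without the alternative, while 25 values of 15 results that were not called did. Over both times Nr4a1 was at -0.031 with upper-quartile scaling, -0.027 with a mean of at least 50 counts and -0.005 without the 286 genes. In the interaction Nr4a2 was at -0.003 with a mean of at least 50 counts, and for time in WT Pdcd1 was at -0.009 with library size alone. Median-ratio and upper-quartile scaling, a mean of at least 50 counts, DESeq2, limma-voom, the replicate block and thinning kept all 6 counts within 1.5 times, and autosomes only kept the 3 genotype counts, the ones it was run for. With the replicate block they were 56, 1285, 938, 0, 1369 and 404, in the order 24 h, 48 h, both times, interaction, time in WT and time in the libraries labelled dKO, and autosomes gave 49, 1357 and 947 for the first 3. Library size alone moved the median log2 fold change of all genes by 0.177 at 48 h, 0.187 for the interaction, -0.359 for time in WT and -0.171 for time in the libraries labelled dKO. It called 2531 genes at 48 h (1615 higher), 3366 for time in WT (725 higher) and 739 for time in the libraries labelled dKO (143 higher). Without a filter the counts were 206 at 24 h, 2962 at 48 h, 2264 over both times, 170 for the interaction and 1649 for time in the libraries labelled dKO. At an adjusted p below 0.10 they were 95, 2891 and 1958 for the genotype comparisons and 931 for time in the libraries labelled dKO, a wider threshold by construction. An absolute log2 fold change of at least 1 left 886 at 48 h, 200 over both times, and 959 and 285 for time in WT and in the libraries labelled dKO. Fitting only the 4 libraries compared gave 181 at 24 h, 444 at 48 h, 31 for time in WT and 4546 for time in the libraries labelled dKO. Without the 286 genes 872 were called at 48 h and 580 over both times, fewer in part because those genes were left out.

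Leaving out 1 library, whose remaining replicate is then assumed to vary like the other groups, gave wide ranges. At 24 h the count ran from 13 (without WT 24 h replicate 2) to 371 (without WT 48 h replicate 2), at 48 h from 15 (dKO 48 h replicate 2) to 6521 (WT 48 h replicate 1), and over both times from 56 (dKO 24 h replicate 1) to 5606 (WT 48 h replicate 1). The interaction ran from 0 to 3459 (WT 48 h replicate 1), time in WT from 595 (WT 24 h replicate 2) to 4212 (WT 48 h replicate 1), and time in the libraries labelled dKO from 32 (dKO 48 h replicate 2) to 3303 (either WT 48 h replicate). Without WT 48 h replicate 1 or 2, the pair with the widest spread no longer enters the pooled error. The log2 fold change of Nr4a2 ran from 1.202 to 1.503 at 24 h and from 1.189 to 1.642 at 48 h. It missed the threshold at 24 h without WT 24 h replicate 1 or 2 (adjusted p = 0.108 and 0.185), dKO 24 h replicate 1 or 2 (0.139 and 0.0881) and dKO 48 h replicate 1 or 2 (0.051 and 0.0511). At 48 h it did so without dKO 48 h replicate 1 (0.137) or 2 (0.149). Nr4a1 was not called at 24 or 48 h in any alternative. It ran from -0.033 (without WT 24 h replicate 2) to 0.917 at 24 h and from -0.187 to 0.289 over both times. Other results not called that turned were Prf1 (-0.164 to 0.064) and Slamf6 (-0.021 to 0.132) at 24 h, Havcr2 (-1.139 to 0.058), Nr4a3 (-0.880 to 0.279) and Slamf6 (-0.226 to 0.538) at 48 h, and Havcr2 (-0.034 to 0.568), Nr4a3 (-0.389 to 0.190) and Slamf6 (-0.085 to 0.297) over both times. In the interaction they were Nr4a2 (-0.147 to 0.306), Nr4a3 (-0.981 to 0.178) and Slamf6 (-0.282 to 0.483), and for time in WT Ifng (-0.377 to 0.092).

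Of 50 called list results, an estimated correlation kept 5, fry 28, the replicate block 47 and the fit without the 286 genes 47. In camera 3 turned direction, with these medians: ribosomal proteins at 24 h ran from -0.033 (without WT 24 h replicate 2) to 0.401, and in the interaction from -0.209 (without WT 48 h replicate 2) to 0.657, and oxidative phosphorylation in the interaction from -0.138 (without WT 48 h replicate 2) to 0.476. Without WT 24 h replicate 1 or 2, 38 and 43 of the 50 kept their call, without dKO 24 h replicate 1 or 2, 40 and 48, without WT 48 h replicate 1 or 2, 41 each, and without either dKO 48 h replicate, 48. A mean of at least 50 counts kept 43, and median-ratio factors, upper-quartile factors and thinning kept all 50. Apart from Nr4a1 and Nr4a2 at 24 and 48 h, there were 6006 alternative values of 285 single-gene results, of which 4954 kept their direction and side of the threshold, 947 were no longer past it, 81 newly passed and 24 turned, 0 of these called; Nr4a1 at 24 h is the remaining 1 of the 25 given above. Depth limits the low end: at the lowest total of 5000952 counts, 3 counts are 0.600 CPM.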

Other observations

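The tests of a common source, of kept exons, of a mislabelled library and of exchanged labels, with the set of 286 genes and its threshold, were chosen only after the result was seen; the tests of repeats, depth and other splits were planned, but the limit to splits balanced over time was set after the result was seen.

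Several gene lists not described so far were called by camera with few or no single genes past the threshold. At 24 h, oxidative phosphorylation genes had a median of 0.17 in the libraries labelled dKO (camera adjusted p = 0.000476, adjusted p = 0.674 with an estimated correlation). Ribosomal protein genes had a median of 0.15 (camera adjusted p = 0.017, adjusted p = 0.776 with an estimated correlation), and ribosome biogenesis genes 0.13 (camera adjusted p = 0.00723, adjusted p = 0.397 with an estimated correlation). In these 3 lists edgeR called 0 genes, with 0 at an unadjusted p under 0.05. Left-out libraries that ended these calls were WT 24 h replicate 2 for oxidative phosphorylation (0.266), WT 24 h replicate 2 (where camera turned direction) and dKO 24 h replicate 2 (0.295) for ribosomal proteins, and WT 24 h or dKO 24 h replicate 1 for ribosome biogenesis (0.156 and 0.133). Interferon response genes had a median of -0.23 at 24 h with 0 of 46 called in edgeR, 3 higher and 7 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0164, adjusted p = 0.606 with an estimated correlation), a call lost without WT 24 h or dKO 24 h replicate 1 (0.763 and 0.444) or without a filter (0.0502). In the fits without WT 48 h replicate 1 or 2, 1 of these genes rose and 4 fell. The 7 CD8 markers had a median of -0.22 (camera adjusted p = 0.0317, adjusted p = 0.594 with an estimated correlation), lost without the same libraries (0.216 and 0.277). Of the 3 NR4A genes, Nr4a2 alone rose (camera adjusted p = 0.017, adjusted p = 0.397 with an estimated correlation), and the list call was lost without WT 24 h replicate 2 (0.169) or dKO 24 h replicate 1 (0.0515). Over both times, the amino acid response genes Asns, which makes asparagine, at 0.94 (SE 0.21) and Cth, which makes cysteine, at 1.68 (SE 0.31) were the 2 of 36 that rose (camera adjusted p = 0.0215, adjusted p = 0.626 with an estimated correlation, 0.0695 without WT 24 h replicate 1 and 0.0861 with a mean of at least 50 counts). Histone genes (3 of 53 rose, camera adjusted p = 4.14e-09, adjusted p = 0.0863 with an estimated correlation) and ribosome biogenesis genes (4 of 43 rose, camera adjusted p = 0.000973, adjusted p = 0.317 with an estimated correlation) were called higher too. So were oxidative phosphorylation genes (1 of 76 rose, camera adjusted p = 7.65e-08, adjusted p = 0.654 with an estimated correlation) and ribosomal protein genes (0 of 75 in edgeR, 4 at an unadjusted p under 0.05, camera adjusted p = 2.07e-07, adjusted p = 0.735 with an estimated correlation). Without WT 48 h replicate 1 the risen counts in these 5 lists were 14, 22, 14, 59 and 62, and without WT 48 h replicate 2 they were 3, 8, 8, 5 and 0. Without any 1 of the other 6 libraries no rise was called in them. Scaled by library size alone, 5 amino acid response, 10 ribosome biogenesis, 8 oxidative phosphorylation and 1 ribosomal protein genes rose. At 48 h alone the amino acid response list (1 rose, camera adjusted p = 0.0587) and the histone list (1 rose, median 0.063, camera adjusted p = 0.136) were not called. At that time 0 histone genes rose and 8 fell without WT 48 h replicate 2 (median -0.014), 11 rose and 1 fell without WT 48 h replicate 1, and the single rise was lost without any other single library and with the replicate block. With library size alone 2 histone and 7 amino acid response genes rose at 48 h, and the second list was called (camera adjusted p = 0.0497). At 24 h alone the amino acid response list was not called either (camera adjusted p = 0.138).

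At 48 h the chemokine receptor genes Ccr2 at 2.11 (SE 0.409) and Cxcr3 at 0.93 (SE 0.209) were among the 3 of 19 trafficking genes that rose in the libraries labelled dKO. The list was not called (median -0.225, camera adjusted p = 0.982), and its single-gene calls were lost without either dKO 48 h replicate. With time in WT, ribosome biogenesis genes were lower (median -0.15, camera adjusted p = 0.0464, adjusted p = 0.589 with an estimated correlation), a call lost without WT 24 h replicate 2 (0.0955), WT 48 h replicate 1 (0.195) or dKO 48 h replicate 1 or 2 (0.0534 and 0.0549), and with the replicate block (0.0544) or without the 286 genes (0.0624). With time in the libraries labelled dKO, histone genes were lower, with 4 of 53 fallen (median -0.35, camera adjusted p = 0.000539, adjusted p = 0.186 with an estimated correlation). With a mean of at least 50 counts this median was -0.044 and the call was lost (adjusted p = 0.143). The count of fallen histone genes was 11 without either WT 48 h replicate and 2 without WT 24 h replicate 1, and without any 1 library labelled dKO the single-gene calls were lost. It was 10 with library size alone and 2 with the replicate block. Negative feedback genes were lower, with 2 risen and 6 fallen of 30 (camera adjusted p = 0.0194, adjusted p = 0.208 with an estimated correlation, 0.053 and 0.0506 without WT 48 h replicate 1 or 2). Of these genes 4 rose and 14 fell without either WT 48 h replicate, and 1 rose and 1 to 3 fell without 1 library labelled dKO. Library size alone gave 10 fallen. Oxidative phosphorylation genes (camera adjusted p = 2.75e-06, adjusted p = 0.676 with an estimated correlation) and ribosomal protein genes (camera adjusted p = 0.00255, adjusted p = 0.798 with an estimated correlation, 0.068 without dKO 24 h replicate 1) were called as lists, while 0 of 76 and 0 of 75 passed in edgeR (9 and 1 higher at an unadjusted p under 0.05). Of the first, 31 and 30 rose without WT 48 h replicate 1 or 2 and 1 without either WT 24 h replicate, and of the second 7 without either WT 48 h replicate. Lists not called at 48 h include S phase (2 rose and 2 fell of 46, adjusted p = 0.321), heat shock and unfolded proteins (0 and 2 of 30, adjusted p = 0.203), interferon response (3 and 1 of 46, adjusted p = 0.962) and type 2 and type 17 genes (adjusted p = 0.962). With library size alone 5 S phase genes, 5 heat shock and unfolded protein genes and 8 interferon genes rose, and with the replicate block 1 interferon gene. Neighbours of Nr4a1 and Nr4a2 had an adjusted p of 0.979, the B, myeloid and red, platelet or stromal markers 0.962, 0.962 and 0.282, and the CD8 markers 0.187. In these lists Cd74, a B cell and antigen presentation gene, rose (0.85, SE 0.24, adjusted p = 0.0499), the myeloid gene Cd14 fell (-1.22, SE 0.237, adjusted p = 0.0162) and Cd2 of the CD8 markers rose (0.56, SE 0.151, adjusted p = 0.0435). Both rises lost their call without any single library other than WT 48 h replicate 1, that of Cd2 with the replicate block, and the fall without either dKO 48 h replicate. Per library, the B markers summed to 12.9 to 19.6 CPM, myeloid markers to 50.7 to 63.4, CD4 and regulatory T markers to 26.7 to 48.9, NK and gamma delta markers to 1.16 to 2.85, and red, platelet and stromal markers to 14.5 to 24.9, against 1239 to 2323 CPM for the CD8 markers.

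At 48 h 1024 genes were lower in the libraries labelled dKO, and 281 of them belong to the 286 genes of a common profile. That profile was set over libraries that include those at 48 h, so the direction of the 286 genes there follows from their choice. Lower genes less often had a B1 repeat match (14.7 against 20.2%, odds ratio 0.58, 95% interval 0.48 to 0.70, with 91.4% of genes annotated). The 286 were not tested alone, so B1 reads stay open. Depth is argued against: 882 genes were called lower with WT 48 h replicate 2 thinned, 860 of them among the 1024. A candidate explanation for the 286 genes is 1 source of reads counted in many genes: chosen on 6 libraries, 99.7% of them were also higher in WT 24 h replicate 1 than in replicate 2, against 47.0% of genes not called. Their counts varied by more than counting error around the profile (chi-square per degree of freedom 8.1), while 251 other genes used as the seed were followed by a median of 18 and at most 163 genes (Dnmt1), so shared regulation stays open, untested, and the source is not identified. Of the 743 other lower genes 64.5% were higher in WT 24 h replicate 1, so a part of their counts from such a source and a difference of the cells themselves cannot be told apart.

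Nr4a2 rose in the libraries labelled dKO and Nr4a1 was not called. A single mislabelled library is argued against, since Nr4a2 was above both WT libraries of the same time in all 4 libraries labelled dKO. Counts from exons that the floxed alleles keep could give this (Nr4a2 at 1.37 over both times, SE 0.123, as a count per gene), as could labels exchanged between whole groups (Nr4a1 at 0.01, SE 0.187). At 24 h Nr4a1 was at 0.37 (SE 0.265), and at 48 h, which goes against an exchange but did not pass, at -0.35 (SE 0.264, adjusted p = 0.38), with 634.60 and 669.48 CPM in the libraries labelled dKO and 881.05 and 778.94 CPM in WT. These cannot be told apart here, because the deleted exons, and whether reads cover whole RNAs or only 5' ends, are not given in the sources used here and no other transcript marks the genotype.

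For the genotype comparison over both times, other splits of the 8 libraries into 4 and 4 were fitted in a model with time and group. Splits with unequal numbers of each time per side are partly confounded with time and were not counted. The real split called 219 genes and the highest of the other splits 0, so 1 of 18 splits gave as many, and 18 splits are too few for a share under 0.05.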
